A study of Mus musculus with 3 samples.

How the data were processed

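RNA from cells labelled as primary endothelial cells of the mouse corpus cavernosum was hybridised to Agilent mouse expression arrays with a single dye, Cy3. Per the labels, RNA of 3 samples was pooled for each of the 3 arrays and the cells were kept for 48 h in 5 or 30 mmol glucose, the latter with or without DKK2. Groups were taken from the sample titles. Per the file headers, the arrays were scanned and quantified with Feature Extraction 11.5.1.1, and the files hold a processed signal intensity per spot, on a linear scale and corrected for background, with flags for spots that are outliers, saturated or not well above background. The deposited value table also holds intensity: its columns equal the scanner's processed signal averaged over spots, within a fraction of 0.001 for 99.7% of probes, with no log, scaling or centring. Its column medians are 101.8 in normal glucose, 196.2 in high glucose and 204.6 with DKK2.

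Each array had 44397 spots, of which 1377 control spots were left out, and 110, 115 and 136 outlier spots in normal glucose, high glucose and DKK2 were left out. No spot was saturated. The main values were log2 of the processed signal minus each array's 75th percentile, averaged over the spots of a probe. A probe was called well above background where at least 50% of its spots were. The 75th percentile of signal was 1201 in normal glucose, 2380 in high glucose and 2417 with DKK2, so the normal glucose array was the dimmer one. Precision came from the scanner's error model and from 399 probes spotted 10 times per array, whose median spot SD was 0.071, 0.074 and 0.081 log2 units where well above background. Both are technical errors.

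Probes were named through their accessions in a RefSeq gene table of another assembly than the one in the file headers, used for names only: 27508 probes matched 1 symbol, 11921 matched none there and are not named here, giving 20886 genes. A gene's value was that of its brightest probe over the 3 arrays among probes well above background on at least 1 array, and a difference was counted where that probe was well above background on both arrays. Genes above background on 1 array of a pair, with no probe above it on the other, got a bound: the bright value against the higher of the dim probe's own value and the lowest signal above background on that array. Between high and normal glucose 1512 genes had such a bound on the higher side, 79 of them at least 2-fold, and 88 on the lower side.

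The 2-fold rule, 28 gene lists and the rule for named genes were fixed before the data were examined. The named genes are, per comparison, the 12 largest rises and falls that were at least 2-fold in the main setting and with normexp and whose other probes lay on the same side of 0, the 3 largest bounds per side, up to 4 members per list and 11 genes of interest; clone and predicted names were left out. Some genes that the rule takes are not reported here. The lists are endothelial identity, lymphatic endothelial, smooth muscle and pericyte, fibroblast, macrophage and leukocyte, Schwann cell and glia, epithelial, Wnt/beta-catenin targets, Wnt ligands, receptors and modulators, angiogenic factors and receptors, neurotrophic factors and receptors, nitric oxide and cGMP signalling, leukocyte adhesion and chemokines, interferon response, matrix and TGF-beta response, Notch pathway, glycolysis, glucose sensing with its side pathways, oxidative stress defence, superoxide-producing oxidases, endoplasmic reticulum stress and amino acid response, p53 targets and apoptosis, cell cycle, cholesterol synthesis, hypoxia response, oxidative phosphorylation, immediate early and heat shock. A list's median was placed among 10000 random lists of the same size drawn in 20 brightness bins and stood apart under the 2.5th or over the 97.5th percentile.

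For the relation of both differences, 100 sets of arrays with no effect were simulated from the spot spread. The counting was tested on simulated data with 200 genes changed: of 100 genes changed by 1.5 log2 units, 98 were recovered between high and normal glucose (16773 genes), 99 between DKK2 and high glucose (17825 genes) and 100 between DKK2 and normal glucose (16678 genes). Spot noise alone carried 62, 164 and 95 unchanged genes past 2-fold. All probes of a gene got the same simulated change and the only noise was spot spread, so these values test the counting. They do not give the recovery or the false calls on the real arrays, where probes of 1 gene can disagree.

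Alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, cyclic loess, no filter on dim probes, a stricter filter (signal of at least 100 on all arrays), the mean over probes, the deposited table, and size rules of 1.5-fold and 3-fold. Normexp used the median signal and the local median background; the mean signal was not used here. Tools were R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.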

Results

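Gene expression was measured on 3 one-colour microarrays of cultured cells labelled as endothelial cells from the mouse corpus cavernosum, the erectile tissue of the penis. One array held cells in normal glucose (5 mmol as labelled), 1 held cells in high glucose (30 mmol) and 1 held cells in high glucose with added DKK2 protein, each after 48 h. DKK2 (Dickkopf 2) is a secreted modulator of Wnt signalling, and its dose is not given in the sources used here. RNA of 3 samples was pooled for each array, so there was 1 array per condition, no replicate check and no p-value. The number of arrays limits the precision, and array position on the shared slide and condition cannot be told apart. The median processed signal was 101.8 in normal glucose, 196.2 in high glucose and 204.7 with DKK2, and 76.6%, 84.7% and 83.9% of the 39429 probes were well above background. Of 30 endothelial identity genes, 13 were kept by the stricter filter (signal of at least 100 on all arrays). The median over all probes in normal glucose, 101.8, was close to that bound, so many probes of other genes fall under it too. In high glucose the signal of Tek and Nos3, from that list, was 118 and 463. That of the smooth muscle and fibroblast markers Acta2 and Fap was 50085 and 18584, but that of the smooth muscle marker Des was 83. These are signals of different probes and were not converted to amounts. The share of each cell type was not measured. A log2 difference between 2 arrays carried a technical error of 0.20 (median SD from the scanner's error model), which does not include variation between cultures. Nor does it cover disagreement between probes of 1 gene: in the glucose comparison the differences of 2 probes correlated across genes at 0.22. Below, "higher" and "lower" for a count of genes mean at least 2-fold.

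The first comparison addressed what high glucose did to expression. Angpt1, which encodes the vessel-stabilising ligand of the Tie2 receptor, was lower in high glucose by a log2 difference of -3.08 (error SD 0.20), while Angpt2, its context-dependent antagonist, was higher by 1.45. The chaperone-related genes Sdf2l1 and Pdia4 were higher by 3.30 and 3.17 (1.80 and 2.04 with normexp background correction). Their list, endoplasmic reticulum stress and amino acid response, lay inside the random lists (median 0.18, 69.6th percentile), with 2 of 29 higher and 3 lower. Haptoglobin (Hp), an acute phase plasma protein, was higher by 2.66, and the endothelial guidance receptor gene Robo4 was higher by 2.26 (0.88 with normexp). Endogenous Dkk2 was lower by -1.56. For Angpt1, Angpt2 and Dkk2 no other probe was measured on both arrays.

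Of 16766 genes measured on both arrays, 448 were higher and 960 lower in high glucose. Among the lower genes with the largest differences were the olfactory receptor gene Olfr502 at -3.65, Tmem138 at -3.30, Padi6 at -3.29 and the vomeronasal receptor gene Vmn1r197 at -3.04; with normexp these were at -2.16, -2.90, -2.17 and -2.45 in that order. The largest rises included Fam13c at 3.92 (2.23 with normexp), the small nuclear RNA gene Rnu2-10 at 3.61 (1.35), Ttc5 at 3.40 (2.18), Rsl24d1 at 3.20 (2.01), Lrrc2 at 3.00 (1.58), Prcc at 2.88 (2.22), the proteasome subunit gene Psmb2 at 2.78 (2.38) and Ube2q2 at 2.68 (1.73). With the stricter filter on dim probes Fam13c was at 0.50 and Rsl24d1 at 0.67, each read on another probe of the gene. Acot2, an acyl-CoA thioesterase gene, was well above background in high glucose only and at least 16.4-fold higher, and Adam34 was at least 17.6-fold lower.

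Of the 28 gene lists, 2 stood above random lists of matched brightness and 0 stood below them. With lists drawn gene by gene at random, 1.4 would fall outside. Members of a real list can move together and some lists share genes, so 1.4 does not test this count. The 27 measured endothelial identity genes had a median difference of 0.47, at the 99.98th percentile of 10000 random lists, a description of these arrays only. In that list 5 genes were higher and 0 lower, with Icam2 at 2.56 and Mmrn2 at 1.76 (0.89 and 0.92 with normexp), but with the stricter filter on dim probes the list lay inside the random lists. The 42 oxidative phosphorylation genes had a median of 0.34 (99.64th percentile), with 35 of 42 above 0, 3 higher and 1 lower: Uqcrfs1 was at 1.11 and the lower gene, Uqcrc1, at -2.24. Macrophage and leukocyte markers had a median of 0.25 (88.80th percentile). A further list of macrophage genes, chosen after the largest differences were seen, had a median of 0.58 (100th percentile), with 18 of 19 above 0, 5 higher and 1 lower. An adipocyte list, also chosen after the largest differences were seen, had a median of 0.43 (99.41th percentile), with 5 of 19 higher and 0 lower. Some of its genes were among the 50 largest falls with DKK2, a choice that favours genes reading high on the high glucose array. Fibroblast markers had a median of -0.09 (8.08th percentile). Cell cycle genes (median 0.15), cholesterol synthesis genes (median -0.05) and Wnt/beta-catenin target genes (median 0.02) lay inside the random lists. Members with large differences in other lists were Tgfb1 at -1.97, Trp53 at -1.79, Lfng at -2.64, Lif at -2.59 and Saa3 at 1.92 (1.31 with normexp). The glucose-induced gene Txnip was at 0.84 (0.37 with the mean over probes) and Vegfa at 0.04 (-0.58 with the mean over probes), both with probes that disagreed in sign. Nos3, the endothelial nitric oxide synthase gene, was at 1.26 (0.19 with normexp), and Lrp5 and Lrp6, the Wnt co-receptors that DKK2 binds, were at -0.78 and -0.21 (Lrp6 at -0.52 with the mean over probes).

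Probes of one gene agreed poorly in this comparison. Of 299 genes at least 2-fold apart that had another measured probe, 102 (34.1%) had probes on both sides of 0, and over 4294 genes with a second probe measured on all 3 arrays the glucose differences of both probes correlated across genes at 0.22 (genes are not independent replicates). With normexp background correction 172 genes were higher and 3931 lower, and the median of all genes moved from 0.09 to -0.26. The fixed offset in normexp weighs more on the dimmer normal glucose array. By design this draws the differences of dim genes towards negative values here.

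The second comparison addressed what DKK2 changed in high glucose. The medians of the cholesterol synthesis, cell cycle, glycolysis and macrophage and leukocyte lists stood above random lists with DKK2, and those of the fibroblast, matrix and neurotrophic lists stood below. Slco4a1, an organic anion transporter gene, was higher by 4.47, the matrix metalloproteinase gene Mmp10 by 4.04, the keratin gene Krt18 by 3.86 and the stress-induced transcription factor gene Atf3 by 2.96. Adipoq, which encodes the fat cell hormone adiponectin, was lower by -6.20 (-4.18 with normexp).

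Of 17825 genes measured on both arrays, 905 were higher and 865 lower with DKK2. Further large rises were Ranbp3l at 4.74, Ip6k3 at 4.16, the platelet chemokine gene Ppbp at 3.87 and Cnnm1 at 3.44; with normexp these were at 3.18, 2.59, 2.06 and 2.87 in that order. Further large falls were the fast muscle myosin light chain gene Myl1 at -5.47 (-3.17 with normexp), Saa2, an acute phase protein gene, at -4.95 (-2.40), the prolactin receptor gene Prlr at -4.81 (-3.79), Ecrg4 at -4.75 (-4.59), Sult1a1 at -4.60 (-3.86), Mfap4 at -4.32 (-4.03), Hp at -4.23 (-3.79) and Dlk1 at -4.12 (-4.12). With the stricter filter Prlr was at -0.50, read on another probe of the gene. The carbonic anhydrase gene Car3 was not well above background with DKK2 and at least 159.7-fold lower, and Arg2, an arginase gene, was at least 15.8-fold higher.

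In this comparison 10 lists stood above the random lists and 8 below. Of 21 cholesterol synthesis genes 14 were higher and 0 lower (median 1.12, 100th percentile), led by Mvd at 1.98, Lss at 1.82 and Msmo1 at 1.52. Of 38 cell cycle genes 11 were higher and 0 lower (median 0.89, 100th percentile), with Aurka at 1.66, Ccnb2 at 1.64 and Cdc20 at 1.40. Of 22 glycolysis genes 6 were higher and 0 lower (median 0.52, 100th percentile), with Pkm, the muscle-type pyruvate kinase gene, at 1.95 and Pgk1 at 1.28. Macrophage and leukocyte markers moved with these groups: 11 of 17 were higher and 0 lower (median 1.46, 100th percentile), with Fcgr3 at 2.10, Cd14 at 2.03 and C1qa at 1.94. The other lists above the random ones had smaller medians: oxidative stress defence 0.30 (99.94th percentile), p53 targets and apoptosis 0.28 (99.89th), endoplasmic reticulum stress and amino acid response 0.27 (99.72th), hypoxia response 0.27 (98.82th), oxidative phosphorylation 0.20 (98.19th) and lymphatic endothelial 0.66 over 4 genes (98.32th). The lymphatic list was inside the random lists with normexp and without the filter on dim probes and kept under 3 genes with the stricter filter. Hypoxia response was inside with quantile normalization and oxidative phosphorylation with quantile normalization or the mean over probes. Among their members Chac1, a glutathione-degrading enzyme gene, was at 1.80 and Pmaip1, a p53-induced cell death gene, was at 1.34.

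**Figure D1:**
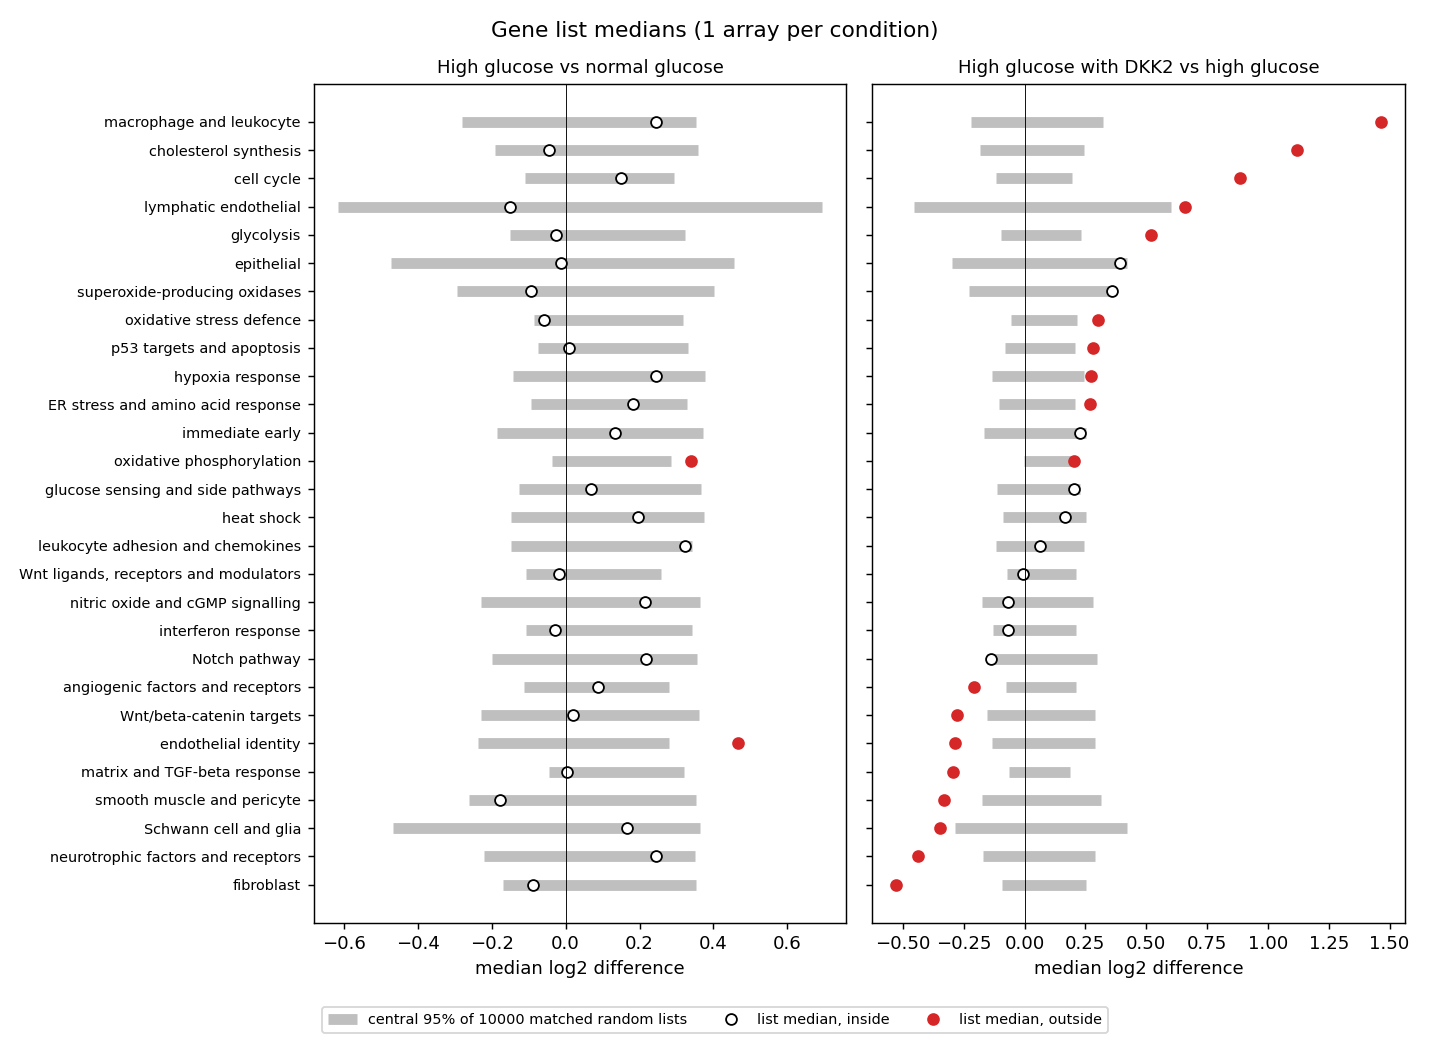
Median log2 difference (x axis) of each of the 28 gene lists (y axis) in both comparisons; grey bars span the central 95% of 10000 random lists of matched brightness, and filled points lie outside them. With DKK2 the macrophage and leukocyte (1.46), cholesterol synthesis (1.12) and cell cycle (0.89) lists lie farthest to the right and the fibroblast list (-0.53) farthest to the left.

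Fibroblast markers had a median of -0.53 (0.00th percentile), with 4 of 16 lower and 0 higher, among them Clec3b at -3.21, Dpt at -2.68 and Postn at -2.44. The matrix and TGF-beta response list had a median of -0.29 (0.00th percentile), with 9 of 39 lower and 1 higher: Ccn2 was at -2.62 and Loxl2, a collagen cross-linking enzyme gene, at -2.00 (-1.32 with the mean over probes), while the metalloproteinase gene Mmp3 was at 1.91. Neurotrophic factors and receptors had a median of -0.44 (0.00th percentile), yet Gdnf was at 1.32 and Gfra1, its receptor gene, at 1.52. Smooth muscle and pericyte markers (-0.33, 0.18th percentile), Schwann cell and glia markers (-0.35, 1.37th percentile) and angiogenic factors and receptors (-0.21, 0.02th percentile) were also below, with Acta2 at -1.67 and Ngfr at -1.31. Lists of other cell types, chosen after the largest differences were seen, had lower medians: skeletal muscle -0.996 and adipocyte -0.88 (both at the 0.00th percentile). These percentiles reuse genes that prompted the choice. In each list 5 members were among the 50 largest falls, and without them the medians were -0.75 and -0.47. Endothelial identity genes had a median of -0.29 (0.11th percentile), with 8 of 29 lower and 2 higher, but with the stricter filter on dim probes this list moved to the other side, to the 91.5th percentile. Wnt/beta-catenin target genes had a median of -0.28 (0.23th percentile), with 5 of 20 lower and 0 higher: Lgr5 was at -3.25, Nkd1 at -2.11 (-1.47 with normexp, -1.36 with the mean over probes) and Axin2 at -0.80 (-0.38 with normexp). That list was inside the random lists with the stricter filter. The Wnt ligands, receptors and modulators were inside the random lists (median -0.01, 13.8th percentile), with 25 of 51 above 0, 4 higher and 7 lower. The lower ones included Sfrp2 at -3.63, Wnt11 at -2.22 and Fzd4 at -2.11.

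The remaining lists lay inside the random lists: epithelial (median 0.39), superoxide-producing oxidases (0.36), immediate early (0.23), glucose sensing, polyol, hexosamine and pentose phosphate pathways (0.20), heat shock (0.17), leukocyte adhesion and chemokines (0.06), interferon response (-0.07), nitric oxide and cGMP signalling (-0.07) and Notch pathway (-0.14). Within them the aldose reductase gene Akr1b3 was at 1.79, the chemokine genes Ccl2 and Ccl5 at 1.43 and 1.69, Oasl1 at 2.04, Hspa4l at 1.90 and Jag1 at -1.63. Angpt1 was at 1.00, Angpt2 at -0.80, Tek, the Tie2 receptor gene, at -1.14 (-0.55 with normexp), Vegfa at 0.69, Lrp6 at -0.91, Lrp5 at 0.16, Kremen1 at -0.24, Nos3 at -0.35, Txnip at -0.40 and endogenous Dkk2 at 0.86.

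Probes of one gene agreed better here than in the glucose comparison. Of 335 genes at least 2-fold apart with another measured probe, 33 (9.85%) had probes on both sides of 0, and the second-probe correlation across genes was 0.64.

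**Figure D2:**
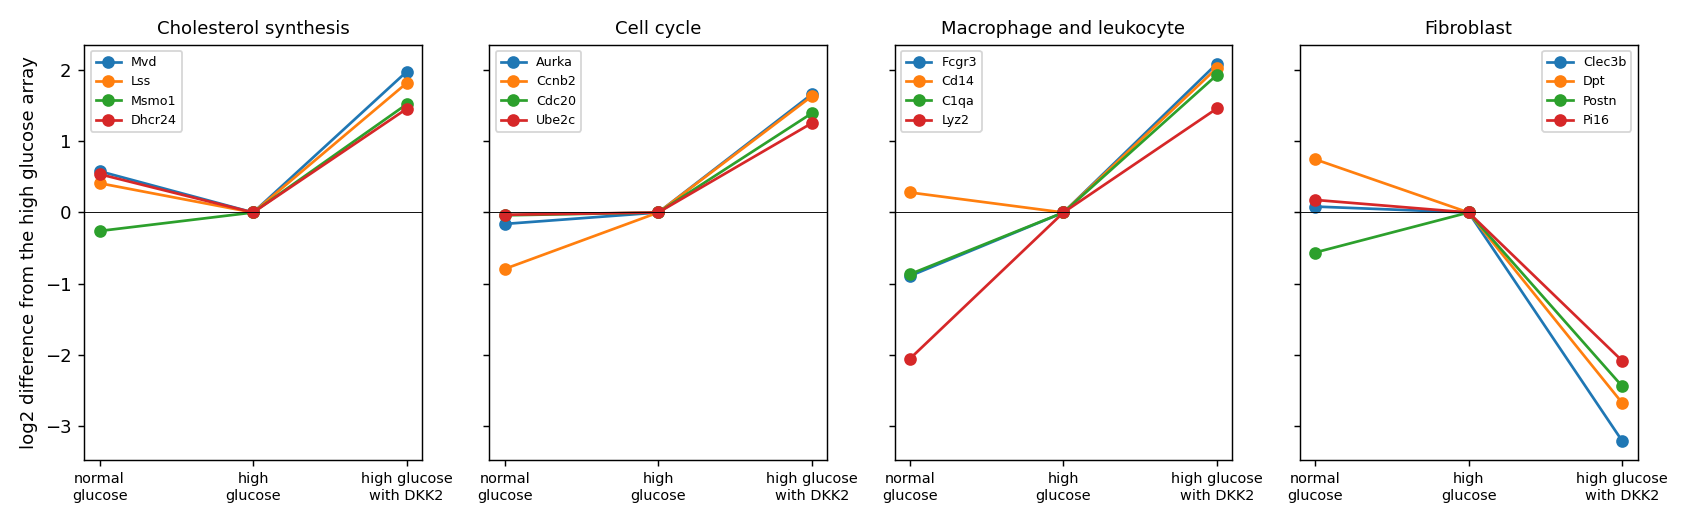
Log2 difference from the high glucose array (y axis) of 16 genes on the 3 arrays (x axis), 1 array per condition; each line is 1 gene. With DKK2 the cholesterol synthesis, cell cycle and macrophage genes lie above the high glucose array (Mvd at 1.98, Aurka at 1.66, Fcgr3 at 2.10) and the fibroblast genes below it (Clec3b at -3.21).

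The third comparison set DKK2 in high glucose against normal glucose. Slco4a1 was higher by 5.57, Krt18 by 4.72, Mmp10 by 4.24 and Sdf2l1 by 4.11, and the interleukin 33 receptor gene Il1rl1 by 3.84; with normexp these were at 3.77, 3.35, 3.65, 2.59 and 3.92 in that order. Adipoq was lower by -6.04 (-4.02 with normexp), Prlr by -5.17 (-4.13, and -0.54 with the stricter filter) and Angpt1 by -2.07 (-2.03). The medians of the cell cycle and cholesterol synthesis lists stood above random lists here as well, and that of the matrix list stood below.

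Of 16676 genes measured on both arrays, 1744 were higher and 1727 lower. Of 36 cell cycle genes 24 were higher and 0 lower (median 1.09), with Ccnb2 at 2.43 and Aurka at 1.82. Of 21 cholesterol synthesis genes 12 were higher and 2 lower (median 1.11), with Msmo1 at 1.78. Macrophage and leukocyte markers had a median of 1.86, with 10 of 16 higher and Lyz2 at 3.52 (2.59 with normexp). The matrix and TGF-beta response list (median -0.65), fibroblast markers (-0.60), Wnt/beta-catenin targets (-0.52) and Wnt ligands, receptors and modulators (-0.38) stood below the random lists, with Loxl2 at -2.70 (-1.59 with the mean over probes), Acta2 at -2.64 and Sfrp2 at -3.60. In all, 7 lists stood above and 6 below, among them the endothelial (median 0.62), epithelial (0.64), hypoxia (0.70) and neurotrophic (-0.40) lists, which all lay inside the random lists with normexp. With the stricter filter the epithelial, hypoxia, neurotrophic and Wnt target lists were inside. With the mean over probes the epithelial and hypoxia lists were inside, with quantile normalization the epithelial list, and without the filter the Wnt ligand list. Among the lists chosen after the largest differences were seen, skeletal muscle had a median of -1.08 (0.00th percentile), with 9 of 18 lower and 0 higher. The adipocyte list had a median of -0.63 (0.07th percentile), with 8 of 18 lower and 0 higher. Both lists were chosen with the largest falls in view, so these percentiles are not separate evidence. Hkdc1, a hexokinase-like gene, was at least 32.1-fold higher. The second-probe correlation was 0.42, and with normexp 938 genes were higher and 4005 lower, with a median of all genes of -0.25.

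The study's title concerns glucose-induced expression and DKK2, so the glucose and DKK2 differences were set against each other. Hp was 2.66 higher in high glucose and then at -4.23 with DKK2, and Robo4 was 2.26 higher (0.88 with normexp) and then at -1.60. An adipocyte list, chosen after the largest differences were seen, also went up and then down. Its median was 0.43 in high glucose (5 of 19 higher, 0 lower) and -0.88 with DKK2 (8 of 18 lower, 0 higher). However, 5 of the 18 genes were among the 50 largest falls with DKK2. Choosing falls favours genes that read high on the shared high glucose array, so this pattern is not separate evidence of a relation. Whether the cell content of the pools or expression within cells moved was not told apart. Of 1360 genes at least 2-fold apart between high and normal glucose that were measured on all 3 arrays, 594 (43.7%, 95% Wilson interval 41.1% to 46.3%, counting error only) had a DKK2 difference of the opposite sign. Among the rises 46.4% ran the opposite way, where 43.3% of all genes had a DKK2 difference below 0, and among the falls 42.4% did, where 56.7% of all genes had one above 0. The high glucose array enters both differences, and simulated arrays with no effect gave 70.3%. That share was taken over the 1360 genes with the largest simulated glucose difference, whatever its size, and the simulation held spot noise only. Across 16653 genes the differences correlated at 0.04, where the simulation gave -0.40, and their covariance was 0.016 against -0.013 simulated.

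Of these genes 60 were at least 2-fold higher in high glucose and at least 2-fold lower with DKK2 (22.4 for independent lists, 4.59 in simulated arrays with no effect), and 38 went down and then up (42.5 and 4.93). In the same direction, 40 were higher in both (20.6 and 0.04) and 65 lower in both (46.1 and 0.01). Independent lists leave out the shared high glucose array and the simulation leaves out the effects, so neither is the value for unrelated effects, and an excess over them is not a shared effect. With normexp the share of opposite signs was 68.1%, where the median glucose difference of all genes was -0.26 and the median DKK2 difference 0.09. Without the filter on dim probes it was 62.6% (72.6% simulated), and the covariance was -0.040 against -0.039 simulated. Where the DKK2 difference was read on another probe of the gene, the share was 49.2% over 295 genes, against 40.7% on the probe that chose them.

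**Figure D3:**
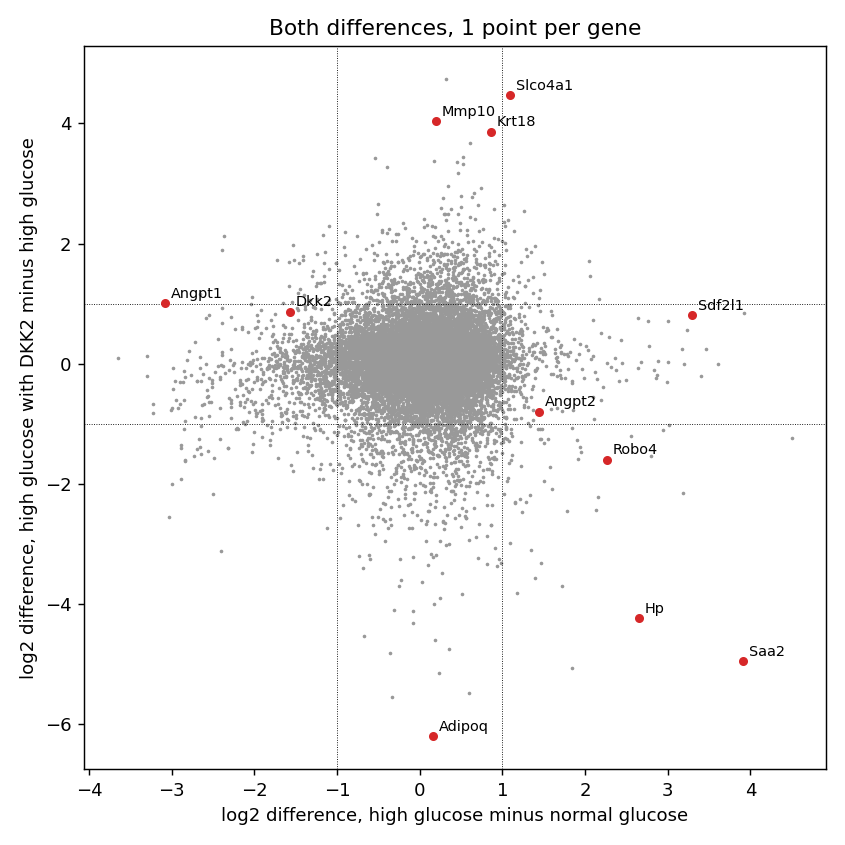
Log2 difference between high and normal glucose (x axis) against log2 difference between high glucose with DKK2 and high glucose (y axis), 1 point per gene, with dotted lines at 2-fold and named genes in red. The cloud has a correlation across genes of 0.04, and Hp lies to the lower right at 2.66 and -4.23.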

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

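The counts in this part were chosen after the data were seen. Probes that matched no gene name in the table used here enter no comparison above, and many were at least 2-fold apart: 1080 between high and normal glucose, 653 between DKK2 and high glucose, and 1710 between DKK2 and normal glucose. They were 295 higher and 785 lower of 8002 measured in the glucose comparison, and 326 higher and 327 lower of 8954 with DKK2 against high glucose. No explanation was tested for them.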

How the results depend on the processing

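The alternatives were fixed before the data were examined. Counts of genes and of lists standing apart under quantile normalization, median scaling, cyclic loess and the deposited table stayed within 1.5 times the main counts. No paired analysis was possible because there is 1 array per condition, and no replicate could be left out. Another size rule or filter changes which genes can count. Normexp added the same offset of 50 on every array before scaling. The 75th percentile of signal was 1201 in normal glucose and 2380 in high glucose, so the offset weighed more in normal glucose. In comparisons with normal glucose, this by design draws the differences of dim genes towards negative values. How much of the normexp changes it accounts for was not tested, nor was the cause of the other changes below. With normexp, genes higher and lower were 172 and 3931 between high and normal glucose, 505 and 478 between DKK2 and high glucose, and 938 and 4005 between DKK2 and normal glucose. Without the filter on dim probes 1103 and 2128 genes differed between high and normal glucose, 1350 were lower with DKK2 than in high glucose and 2674 higher than in normal glucose. With the stricter filter the counts were 219 and 582, 394 and 492, and 1059 and 1138. The 1.5-fold rule gave 2341 and 2276, 2330 and 2012, and 4030 and 3203, and the 3-fold rule 105 and 323, 284 and 321, and 574 and 748. The share of opposite signs was 68.1% with normexp, 62.6% without the filter, 47.5% at 1.5-fold and 36.3% at 3-fold, and the correlation turned to -0.060 with normexp and -0.073 without the filter. Averaging over probes put 4 lists, not 2, outside the random ones between high and normal glucose. Of single list results, 5 lost their place outside the random lists with normexp, 3 with quantile normalization, 8 with the stricter filter (2 of them now on the other side of the middle and 1 with under 3 members left), 3 with the mean over probes and 2 without the filter, of 33 in all.

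With the stricter filter the endothelial identity list moved to the 91.5th percentile between DKK2 and high glucose and the epithelial list to the 30.0th between DKK2 and normal glucose. With normexp the sign turned between high and normal glucose for Aif1 (-0.38), Ccne2 (-1.31), Cldn5 (-0.25), Cxcr4 (-0.95), Egln1 (-1.02), Gucy1a1 (-1.004), Ncf4 (-0.18), Nox1 (-0.41) and Ret (-1.02), and between DKK2 and normal glucose for Cxcr4 (-1.03), Icam2 (-0.066), Jag2 (-0.022), Krt7 (-0.68), Ncf1 (-0.59), Nox1 (-0.039), Sele (-0.90) and Slc7a11 (-0.60). The genes whose sign turned were dim in normal glucose, with signals there from 8.85 (Cxcr4) to 56.7 (Ncf4). All turned to negative values, the direction that the normexp offset of 50 gives dim genes by design. These turns are therefore not separate evidence about the genes. Normexp moved another 173 named values by more than their error, the mean over probes 46, quantile normalization 5 and the stricter filter 5. The moves with the stricter filter were those of Fam13c (0.50 between high and normal glucose, 0.46 between DKK2 and normal glucose), Prlr (-0.50 between DKK2 and high glucose, -0.54 between DKK2 and normal glucose) and Rsl24d1 (0.67 between high and normal glucose). Each was read on another probe of the gene, because that filter dropped the probe used in the main setting. Among the moves with the mean over probes were Prlr (-2.66) and Loxl2 (-1.32) between DKK2 and high glucose and Fam13c (2.21), Ttc5 (1.79), Rsl24d1 (1.93) and Vegfa (-0.58) between high and normal glucose.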

Other observations

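The adipocyte, skeletal muscle, mast cell and receptor lists and the further macrophage list were chosen after the largest differences were seen. Some tests were chosen after their results were seen. These were the tests on fibroblast and endothelial markers, on macrophage genes against lists of matched brightness, on the correlation and on the number of lower receptor genes. Some rules for reading a result were also set after its value was seen. They were the use of the members' spread for adipocyte and muscle genes, the setting aside of cyclic loess and the use of the covariance without the filter. The readings of the second-probe share and of the receptor count were set then too. Between DKK2 and high glucose, 8 of 18 adipocyte genes were lower and 0 higher (median -0.88, 0.00th percentile): Adipoq was at -6.20, Slc36a2 at -3.82, Plin1 at -3.71, Aoc3 at -3.57 and Cfd at -3.32, while Plin4 was at 0.07. Of 19 skeletal muscle genes 9 were lower and 0 higher (median -0.996, 0.00th percentile), with Myl1 at -5.47, Mb at -3.99 and Myh8 at -3.83, while Ckm was at 0.34. The mast cell and basophil list had a median of -0.63 (0.24th percentile), although Mcpt8 was at 3.18. Between high and normal glucose the adipocyte list had a median of 0.43 (99.41th percentile), with 5 of 19 higher and 0 lower.

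Macrophage genes were higher with DKK2, and a larger share of macrophages in the pooled culture is a candidate explanation. A further list of macrophage genes, sharing none with the first, had a median of 1.38, with 18 of 19 above 0; without 4 members that had been seen before or stand in another list it was 1.25. A smaller share of the main cell type would raise all other types alike: if that type is endothelial, as labelled, the fibroblast median of -0.53 argues against it as the whole cause, and if it is fibroblast-like, the endothelial list does, since its upper quartile was at most 0.39 in any setting and the lower quartile of the macrophage list at least 0.78. The lower quartile of that list in the main setting (0.89) lay above the medians of random lists of matched brightness (central 95% up to 0.32). This argues against a difference that shifts genes of like brightness alike. It reuses the comparison that set the list apart, so it is not separate evidence. Cyclic loess left the macrophage median at 1.47, the result set beforehand against a scaling or brightness difference. It moved none of the 412 named values past its error, so by a rule set after the value was seen it decides nothing. Ctss was at 1.85 and Cd14 at 2.03 but Itgam at 0.04 and Cd3e at 0.01; a change of expression within the cells that DKK2 reached stays open and untested, and array position cannot be told apart from DKK2.

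For the fall of adipocyte and muscle genes, fewer cells of these types in the culture may be the source. Outside the 50 largest falls, 13 adipocyte genes had a median of -0.47 and 14 muscle genes a median of -0.75. The adipocyte median passed the bound of -0.5 that had been set against this explanation, by less than the members' spread (quartiles -0.97 and 0.07), and that bound was badly chosen because it left out the genes that fell most. Neither value decides, and a change in the cells' state is as open.

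Noise of the shared high glucose array could make the glucose and DKK2 differences run against each other. In the main setting the correlation of 0.041 across genes and the covariance of 0.016 (-0.013 simulated) ran against noise as the whole relation. The correlation turned to -0.060 with normexp, where nothing was simulated, and without the filter to -0.073 (-0.44 simulated), with 62.6% opposite signs (72.6% simulated); the covariance, which unrelated effects do not dilute, was there nearly that of noise alone (-0.040, simulated -0.039), so noise as the source of the relation stays open. Spot noise would also make the share of opposite signs fall by over 10 percentage points when the DKK2 difference is read on another probe, but the change, counted as a fall, was -8.47: the share rose by 8.47 points (bootstrap interval over genes 2.03 to 14.6), away from what noise predicts. The change also exceeded the 5 points set beforehand for no such noise, and nothing here tested why it rose.

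The receptor genes among the largest falls in high glucose were not matched by a shift of the median of their class. The 389 measured olfactory and vomeronasal receptor genes had a median of -0.03, at the 26.6th percentile of random lists of matched brightness, the result set beforehand for a difference that depends on brightness alone. Of them 47 (12.1%) were lower and 10 higher, while 5.73% of all genes were lower, and random lists held 25 to 47 lower genes in their central 95%, so the count lies at that edge (97.58th percentile) and leaves open whether brightness accounts for it. In 43 receptor probes with a signal of at least 100 on all arrays the median was -0.36, between the bounds set for and against a background offset left on the normal glucose array, so that offset remains open. With DKK2 against high glucose the class had a median of 0.22 (99.91th percentile).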
